A study of Heliconoides inflatus with 11 samples.

How the data were processed

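RNA was measured in whole Heliconoides inflatus, a small shelled pteropod (a swimming sea snail with an aragonite shell), caught with a plankton net of 200 µm mesh and held for 3 d in seawater at pH 8.1 (control, bubbled with ambient air) or pH 7.9 (low pH, bubbled with CO2). Per the labels, each condition had 3 replicate jars, and libraries were sequenced on an Illumina HiSeq2000 as 100 bp paired-end reads. The 11 sequencing runs come from 6 biological samples: 5 samples were sequenced in 2 runs and 1 low-pH sample in 1 run, which gives 6 control and 5 low-pH runs. Per the labels' protocols, sequencing gave an average of 63000000 reads per sample. The depth of each sample is unknown here, so no counting interval or detection floor is given for a contig.

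The only file used was 1 table of the whole series with 5 columns for 21744 contigs, and 0 of its columns hold values of a single sample. Its contents were made by the authors: Bowtie2 and edgeR are named in the submitters' processing notes, and no version, build or annotation is given in the sources used here. The contig names have the form of transcript assembler output, with a component number and a sequence number. Contigs of 1 component are alternative sequences of what the assembler took for the same gene or a closely related one. Per the file headers, the authors deposited a log2 fold change and a mean abundance as log2 CPM (read counts scaled to a common library total) for each contig. The authors also deposited a likelihood ratio, which is used here as a score without fixed range. The p-value and the adjusted p-value of each contig were deposited by the authors as well. From the values, the p-value is the upper tail of a chi-square distribution on the likelihood ratio, with a largest difference of 6.61e-15. The adjusted p-value is the Benjamini-Hochberg adjustment over all 21744 contigs, with a largest difference of 6.73e-15. CPM back-calculated from the mean abundances added up to 1021800 over the table. The low-count filter applied by the authors, their test design, whether the runs of a sample were added together, and which condition is the numerator of the fold change are not given in the sources used here. Signs are therefore reported as the table gives them.

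The design fixed before the data were examined assumed counts per sample, with a quasi-likelihood count test. That test was not used. Without counts, its provision for a deposited comparison was used: the calls of the authors' deposited table at an adjusted p under 0.05 are described, and no new test between the conditions was made. Tests of the preset gene lists (calcification, acid-base balance, nervous system, metabolism, stress, other organisms) were not run, since the table pairs no contig with a gene name or description. Contigs were named by the preset rule: the 2 positive and 2 negative contigs with the smallest adjusted p among those with a mean log2 CPM of at least 1.

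An approximate standard error was computed for each contig as the absolute log2 fold change divided by the square root of the likelihood ratio. It carries the spread between the columns that the authors fitted, and is a poor guide where a group has no reads. In such contigs the fold change of a count model is set by the small count added to every library (the default of 0.125 in the authors' tool edgeR was assumed), so that it rises with abundance along a limiting line. A contig called at an adjusted p under 0.05 was taken to be at that limit when its fold change lay within 0.25 (log2) of the line. Contigs that were not called were not considered. The line was fitted separately on each side of 0. It was the median over the 3 contigs with the largest fold change for their abundance, at a mean log2 CPM of at least 1. Some of these contigs therefore lie at the limit by construction. The counting and the limit detection were tested on simulated data. In a simulated table of 21744 contigs with 200 changed by 3 on the log2 scale, 92.5% of the changed contigs were called, and 3.65% of the calls were unchanged contigs. The fold changes of that table were drawn with the same standard errors that its test used. Both shares therefore check the computation only and are no error rates of the authors' calls. In simulated counts with 3 against 3 or 6 against 5 libraries, 100% of contigs without reads in 1 group were found at the limit, along with 0 contigs that had reads in both groups. The other simulated contigs had equal means in both groups, and many contigs without reads were placed on each side. These counts therefore could not show how contigs with large changes are sorted, nor how the fit behaves with few contigs at the limit.

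Alternatives were stricter thresholds (0.01, 0.001 and Bonferroni), a minimum fold of 2 or 4, a minimum mean log2 CPM of 1, a rescaled likelihood ratio, components in place of contigs, and removal of contigs at the limit. Shares have 95% Wilson intervals, which treat contigs as independent and cover counting only. Computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.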

Results

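Gene expression was compared between whole pteropods kept for 3 d at pH 8.1, close to present surface seawater, and at pH 7.9, the near-future condition that the study addressed. Each condition was represented by 3 biological samples. The authors' deposited table gives 1 comparison over 21744 assembled contigs in 17715 components, of which 14682 components held 1 contig and 3033 held more. Mean abundance in the authors' deposited table ran from -2.54 to 16.01 log2 CPM, with a median of 2.14. The 5 most abundant contigs took 17.6% of the summed CPM. The contigs carry no gene names, so that groups of contigs are described by direction, size, abundance and component. Positive and negative refer to the sign in the table, whose header does not say which pH is the numerator.

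At an adjusted p under 0.05 in the authors' deposited edgeR likelihood ratio test, 573 contigs were called, 400 of them with positive and 173 with negative fold changes. How repeat runs entered that test is not stated. If they were separate columns, 11 runs of 6 samples were counted as replicates, and the p-values may be too small. The positive share was 69.8%, with a Wilson interval from 65.9 to 73.4%. The changes were large. The median absolute log2 fold change of called contigs was 2.89, with quartiles of 2.11 and 4.73, and 458 of the 573 differed at least 4-fold. Fold changes were larger on the negative than on the positive side, with medians of 6.21 and 2.56 on the absolute log2 scale, or 3.85 and 2.55 without contigs whose fold change is set by the added count (contigs at the limit). At least 16-fold changes were found in 111 of 173 negative and 63 of 400 positive contigs, and absolute log2 fold changes of 10 or more in 45 negative and 2 positive contigs. Without the contigs at the limit, the counts were 54 of 116 negative and 60 of 397 positive contigs at 16-fold or more, and 12 negative and 0 positive contigs at a log2 of 10 or more. Contigs near the limit remained in these counts and in the medians without contigs at the limit. Of these, 10 negative ones lay 1.17 to 1.46 (log2) short of it and 5 positive ones 1.06 to 2.01 short. Their sizes may still depend largely on the added count. The excess of positive calls over all contigs shrank under stricter settings. At an adjusted p under 0.01 in the deposited edgeR test there were 213 positive and 122 negative calls, and under 0.001 there were 110 and 92. The excess was absent under the 2 strictest settings, where most of the negative calls were contigs at the limit. With Bonferroni adjustment 80 positive and 79 negative contigs remained in the deposited ranking. To allow for repeat runs, the likelihood ratio was also multiplied by the number of samples over the number of runs, an adjustment chosen after seeing the data. With it, 147 contigs were left, 73 positive and 74 negative. Of these, 53 negative and 3 positive contigs with Bonferroni adjustment, and 51 negative and 3 positive contigs with the multiplied ratio, were at the limit. The calls away from the limit were 77 positive and 26 negative (74.8% positive) and 70 positive and 23 negative (75.3%), against 397 and 116 (77.4%) in the main calls.

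**Figure D1:**
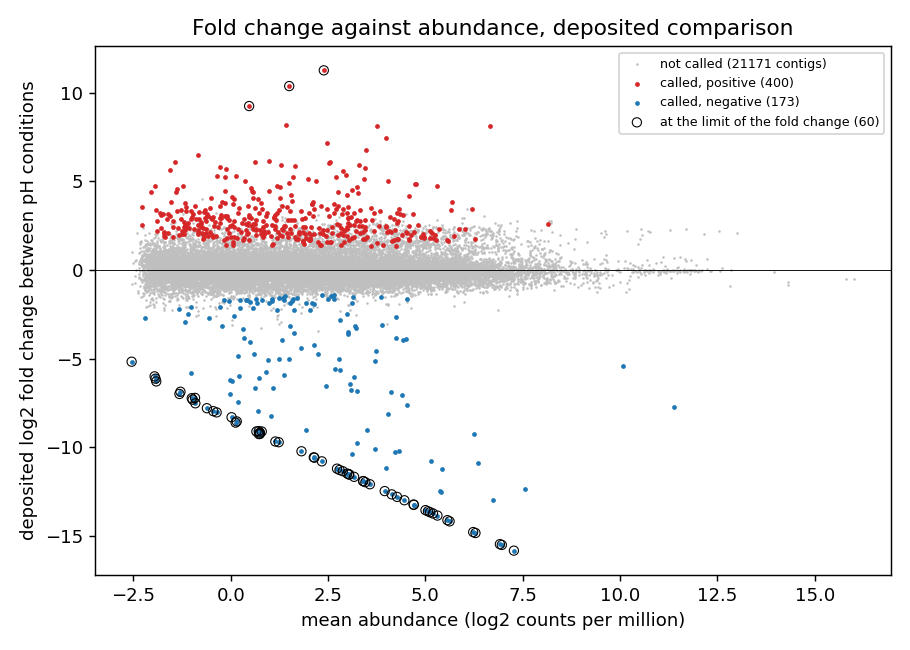
Deposited log2 fold change (vertical axis) against mean abundance in log2 CPM (horizontal axis), 1 point per contig; grey points were not called, red and blue points were called at an adjusted p under 0.05 with positive (400) and negative (173) fold changes. Circles mark the 60 contigs at the limit of the fold change, 57 of them on the lower line and 3 above 0.

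The 2 positive contigs with the smallest adjusted p were comp483392_c0_seq1 and comp251688_c0_seq1. The log2 fold change of comp483392_c0_seq1 in the authors' deposited table was 6.77 (approximate SE 0.77), at a mean abundance of 3.47 log2 CPM and an edgeR adjusted p of 3.71e-14. It was the only contig of its component in the table. For comp251688_c0_seq1, the authors' deposited table lists a log2 fold change of 11.26 (approximate SE 1.29) at 2.39 log2 CPM, with an edgeR adjusted p of 3.71e-14. This fold change was classed as at its upper limit, as was that of the only other contig of this component. The upper line was set by these most extreme positive contigs, so that this largely follows from the fit. The 2 negative contigs with the smallest adjusted p, comp459661_c0_seq5 and comp459661_c0_seq4, belonged to 1 component. In the authors' deposited table, comp459661_c0_seq5 had a log2 fold change of -10.89 (approximate SE 1.53) at 6.36 log2 CPM, with an edgeR adjusted p of 2.70e-09. For comp459661_c0_seq4 the authors' deposited table lists -15.45 (approximate SE 2.31) at 6.91 log2 CPM, with an edgeR adjusted p of 2.92e-08. The value of comp459661_c0_seq4 was at the limit, so that its size depends on the added count and is no measured ratio. The component held 3 contigs, and 3 of them were called with negative fold changes.

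Contigs at the limit of the fold change made up a distinct group. On the negative side, 57 contigs from 55 components lay at the limit, which is 32.9% of the negative calls. On the positive side, 3 contigs from 2 components did, or 0.75% of the positive calls. For 2 of these 3, the most extreme positive contigs, this largely follows from the fit of the line. The negative group spanned mean abundances from -2.54 to 7.27 log2 CPM with a median of 2.73, and 17 of its 57 contigs had 4 log2 CPM or more. That share of 29.8% compares with 26.4% among all contigs, but the group holds called contigs only. Without the 60 contigs at the limit, a removal chosen after seeing the data, 513 calls were left, 397 positive and 116 negative, and the positive share was 77.4%.

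Calls were less frequent among abundant contigs. Of 4816 contigs below 0 log2 CPM, 138 were called, a share of 2.87% (Wilson interval 2.43 to 3.38%), and 112 of these were positive. From 0 to 2 log2 CPM 186 of 5638 contigs were called, with 127 positive. From 2 to 4 log2 CPM 157 of 5539 were called, with 107 positive. From 4 to 6 log2 CPM the share was 1.93% (1.55 to 2.41%), or 76 of 3935 contigs, with 49 positive. From 6 to 8 log2 CPM it was 0.936% (0.548 to 1.59%), or 13 of 1389 contigs, with 4 positive and 9 negative. Of the 9 negative ones, comp459661_c0_seq4, comp510051_c0_seq1, comp465411_c0_seq2, comp510608_c0_seq1 and comp390411_c0_seq1 were at the limit. The 3 contigs of the component of comp459661_c0_seq4 were all among the 9. The 13 calls therefore show no turn towards negative changes away from the limit. At 8 log2 CPM or more, 3 of 427 contigs were called, with 1 positive and 2 negative. The smallest change that was called corresponded to 2.58-fold. The median approximate SE was 0.579 below 0 log2 CPM and between 0.44 and 0.481 in the classes above.

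**Figure D2:**
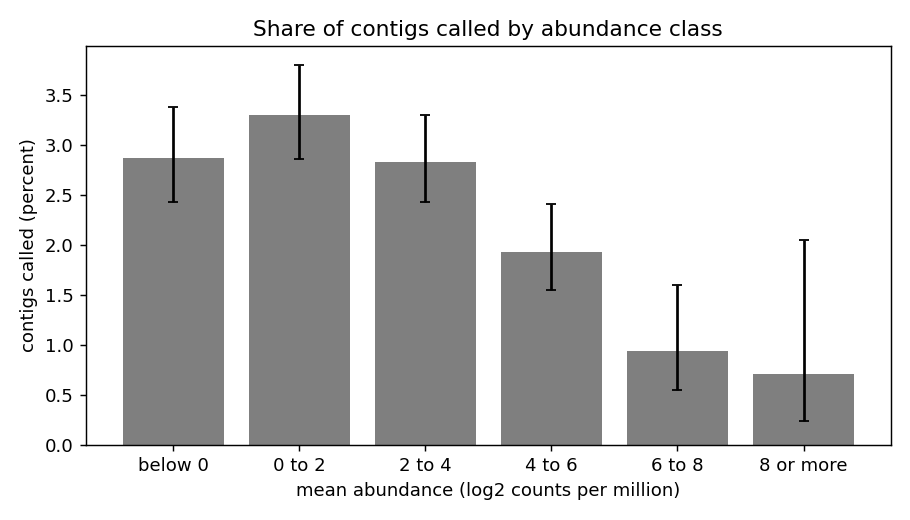
Share of contigs called at an adjusted p under 0.05 (vertical axis, percent) in 6 classes of mean abundance (horizontal axis, log2 CPM). Bars are shares and whiskers are 95% Wilson intervals; the share is 2.87% in the lowest class, 0.936% between 6 and 8, and 0.703% at 8 or more.

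Among the most abundant transcripts, those at 10 log2 CPM or more, most fold changes were small. These 149 contigs held 53.6% of the summed CPM. Their median log2 fold change was -0.03, with quartiles of -0.08 and 0.09, and 104 of the 149 lay within 0.25 of 0. Of the 149 contigs, 2 were called, and the fold changes of these 2 were negative and large, at -7.74 and -5.40 (log2). The median approximate SE of these contigs was 0.472, so that their fold changes were closer to 0 than the standard errors would give.

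A further group of contigs had positive fold changes that mostly did not pass the test. The range of log2 fold changes that defines it, 1.8 to 2.5, was not part of the design fixed before the data were examined. The counts below therefore describe that range and are no test of an excess. Over the whole table, 681 contigs had log2 fold changes between 1.8 and 2.5, of which 139 were called, against 72 contigs between -2.5 and -1.8, of which 17 were called. At 2 log2 CPM or more the counts were 420 with 55 called, against 19 with 5 called. At 4 log2 CPM or more, 258 contigs from 226 components lay in the positive range, against 6 contigs in the negative range. At an adjusted p under 0.05 in the authors' deposited edgeR table, 21 of the 258 positive and 0 of the 6 negative contigs were called. At an unadjusted p under 0.05 the counts were 218 and 4. The median log2 fold change of the 258 contigs was 2.09 and their median approximate SE 0.919. The approximate SE of contigs of the same abundance with absolute log2 fold changes under 1 was 0.437, and that of the 6 negative contigs was 0.879. At 6 log2 CPM or more, 88 contigs lay in the positive range and 1 in the negative range, and 1 of the 88 was called.

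**Figure D3:**
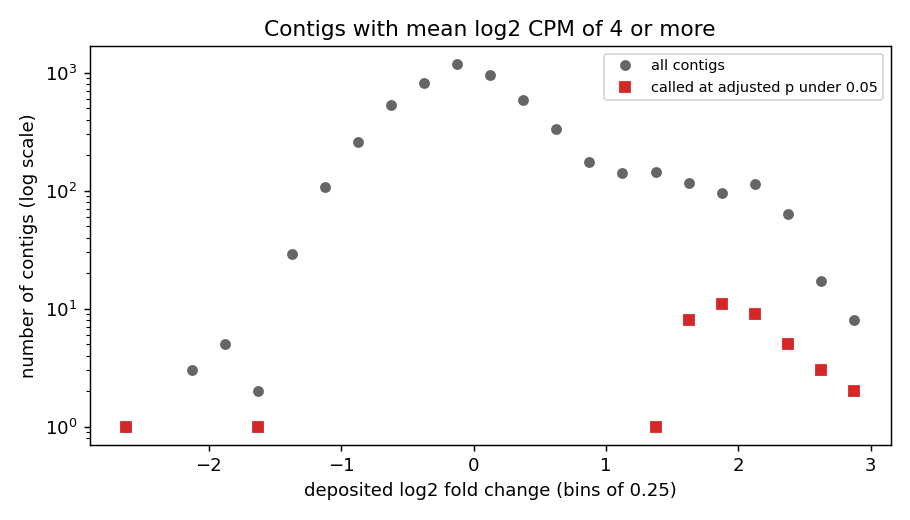
Number of contigs (vertical axis, log scale) by deposited log2 fold change (horizontal axis, bins of 0.25) among contigs with a mean abundance of 4 log2 CPM or more; grey circles are all contigs and red squares those called, and empty bins are not drawn. Between 1.8 and 2.5 there are 258 contigs, against 6 between -2.5 and -1.8.

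Contigs of 1 component mostly moved together. The 573 called contigs came from 499 components, 344 with positive and 156 with negative calls, and 1 component had calls in both directions. Among the 2430 components with 2 contigs in the table, the fold changes of the pair correlated across components with a Pearson r of 0.90 and a Spearman rho of 0.90. The signs were equal in 89.5% of these pairs, against 50.2% when partners were shuffled between components. Where both contigs of a pair were called, 46 of 47 pairs had equal signs. Contigs of 1 component can share reads, so that these pairs are not independent measurements, and components are not replicates.

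Over the whole table, the median log2 fold change was 0.02. An unadjusted p under 0.05 was found for 3190 contigs, or 14.7%, and the p-values above 0.5 correspond to an estimated 81.3% of unchanged contigs. That estimate assumes evenly spread p-values among unchanged contigs. Contigs at 10 log2 CPM or more depart from this, with a median likelihood ratio 0.0753 times that of a chi-square distribution, so that the estimate is rough. The median likelihood ratio was 1.64 times that of a chi-square distribution. Without values per sample, neither a replicate check nor other splits of the samples could be computed. The p-values are the authors', and what spread they measure depends on how the repeat runs entered the fit.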

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

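Of the 11 alternatives, 5 (components, rescaled likelihood ratios, the recomputed adjustment and the removal of contigs at the limit) were chosen after seeing the data. The count of 573 calls, 400 positive and 173 negative (69.8% positive), was 573 with a minimum fold of 2, 458 with a minimum fold of 4 and 499 when components were counted. At an adjusted p under 0.01 there were 335 calls, 213 positive and 122 negative (63.6% positive). At an adjusted p under 0.001 there were 202 calls, 110 positive and 92 negative (54.5%). With Bonferroni adjustment there were 159, 80 positive and 79 negative (50.3%). At a mean log2 CPM of at least 1 there were 335, 221 positive and 114 negative, and with the adjustment recomputed over these contigs 316, 206 positive and 110 negative (65.2%). With the likelihood ratio divided by its median ratio of 1.64, 195 were left, 105 positive and 90 negative (53.8%). With the likelihood ratio multiplied by 0.545, the number of samples over the number of runs, 147 were left, 73 positive and 74 negative (49.7%). No positive majority over all contigs remained. The contigs at the limit account for this, since 51 of the 74 negative and 3 of the 73 positive calls were at the limit, and the calls away from it were 70 positive and 23 negative (75.3% positive, Wilson interval 65.6 to 82.9%). Without the contigs at the limit, the positive share of the main calls rose to 77.4%. In a split of the calls made after seeing the data, the positive share away from the limit was 76.4% at an adjusted p under 0.01, 74.3% under 0.001, 74.8% with Bonferroni adjustment and 74.5% with the likelihood ratio divided by its median ratio. Fewer contigs pass a stricter limit by construction. The 4 named contigs stayed under an adjusted p of 0.05 in the 4 alternatives that recompute it, with values from 2.43e-14 to 0.000959. These alternatives keep the order of the likelihood ratios, and the contigs were named for the smallest values, so that this is no independent check. No paired analysis was possible because the table holds no values per sample. For the same reason recalculations set before the data were examined, on normalization, test, low-count filter, sequencing runs, thinning, left-out replicates, gene lists and the spread between runs were not run. Depth per sample is unknown, and changes under 2.58-fold were not called at any abundance.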

Other observations

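All tests in this part were chosen after the results they bear on were seen. On the negative side 57 contigs lay at the limit of the fold change, against 3 on the positive side. Shallower sequencing of the group without reads would remove scarce transcripts first, and 17 of the 57 had a mean abundance of 4 log2 CPM or more, which argues against depth as the whole cause. Reads assigned to an alternative contig of the same component would leave that contig with a positive fold change, and 0 contigs of these components had one, which bears on the 4 contigs with another contig of their component in the table away from the limit. For the other 53 contigs, reads assigned to a contig outside the table or in another component cannot be told apart from absence, because the table holds neither sequences nor names. A response to pH stays open, as do differences between the animals of the jars and transcripts of other organisms, none of which could be tested.

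The excess of positive log2 fold changes between 1.8 and 2.5 comprised 681 contigs against 72 on the negative side over the whole table (139 and 17 called), and 258 against 6 at 4 log2 CPM or more (21 and 0 called). A scaling difference between the groups would move the other contigs as well, and the median over contigs of that abundance was -0.019. The fold changes were already scaled to library totals, so that this shows only that no shift common to these contigs remained. At that abundance the 258 contigs came from 226 components, which argues against a few genes counted many times. Their approximate SE was 2.03 times that of contigs with small changes, after allowing for the growth that a fold change of this size brings at unchanged spread, but contigs picked for large fold changes favour a large SE, and the 6 negative contigs had 0.879 against 0.919. Large differences between samples therefore cannot be told apart from an effect of pH, because the table has no values per sample.

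Below the negative limit, 10 called contigs lay 1.17 to 1.46 (log2) short of it, and after a gap of 0.591 a series of 15 called contigs ran from 2.05 to 3.11 with spacings of at most 0.144, so that no further step could be set apart. On the positive side, whose limit rests on 3 contigs, 5 called contigs lay 1.06 to 2.01 short without such a gap. A single read in the group otherwise without reads lowers the limit by 1.87 with 3 libraries of equal depth, by 1.38 with 5 and by 1.22 with 6, and 2 reads lower it by 2.66, 2.07 and 1.87. The median first step of 1.39 on the negative side is close to the 1.38 of runs entered as 5 separate columns. The same first step would come from 3 columns 1.64 times deeper than the mean of all libraries. The columns of the other group would then have to lie well below that mean, and the depths are unknown. If runs were entered as separate columns, repeat runs were counted as replicates. The 147 calls after scaling by samples over runs include 51 of the 57 negative contigs at the limit. That scaling keeps the spread of the authors' fit, so that it is unknown whether 147 is the closer count.

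The sign of the table might be read from the same limits, which lay 0.41 higher on the positive than on the negative side at matched abundance (0.36 to 0.45 over 3 contigs). Simulated libraries of unequal depth gave a median offset of 0.25 (95% of draws from 0.15 to 0.37) with 6 columns in the group that negative values favour and 5 in the other, and of 0.01 (-0.16 to 0.19) with 3 columns each. The direction of the offset is what positive values meaning higher at pH 7.9 would give, since that condition had 5 runs. These ranges assume an SD of 0.3 in log depth and a dispersion (spread beyond counting) of 0.4, with contigs drawn independently. The observed median offset lies above both ranges, but its lowest contig lies inside the range for 6 and 5 columns. The offset rests on 3 contigs of 2 components, so that the sign was not settled.

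At 10 log2 CPM or more the median likelihood ratio was 0.0753 times that of a chi-square distribution, against 1.78 times between 0 and 2 log2 CPM.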
